A study of Mus musculus with 12 samples.

How the data were processed

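Whole kidneys of Pod-TRECK mice were compared at 4 stages, with 3 biological replicates per group per the series design text: controls without toxin, and 5, 14 and 21 days after 100 ng of diphtheria toxin given intraperitoneally. Per the labels' protocols, total RNA was extracted from whole kidney with DNase treatment and libraries were made after poly(A) selection. Sequencing was paired-end on an Illumina NovaSeq instrument, per the series design text. All libraries carry 1 batch label.

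The authors deposited 1 table of raw counts of reads per gene, with 56722 genes and 12 libraries, gene identifiers, symbols and coordinates. Per the submitters' processing notes, reads were processed with fastp 0.20.0, counted with featureCounts, and the genome build was GRCm39. The aligner, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Reads of paralogs, pseudogenes, overlapping genes and antisense partners may therefore be shared, and coordinates are given as in the table. Of the genes, 2803 had no symbol and held 2.14% of the counts. They were tested but not named.

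Each column was matched to a sample by its name, and groups and replicate numbers came from the sample titles. Total counts per library ran from 31023852 to 46420299. No libraries were identical, and the lowest chi-square per degree of freedom between libraries of 1 group was 4.9, above sampling noise. This was for day-14 replicates 1 and 2, and the next lowest was 12.62, for control replicates 1 and 3. Ratios of genes with few control counts pool the counts of all libraries of a group and are given with exact 95% counting intervals. Because the counts are pooled, the intervals cover counting error only and leave out differences between mice. The reads also carry no molecular identifiers. These ratios are relative to library totals without TMM factors, so they are not on the scale of the fold changes of the fit.

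Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr, which left 19821, and library sizes were scaled by TMM factors. A quasi-likelihood negative binomial model with 1 coefficient per group was fitted to all 12 libraries, so that the groups shared 1 estimate of the spread. Each day was compared with control and with the other days, 6 comparisons in all, and the 3 day coefficients were tested jointly. P-values were adjusted by Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Log2 CPM values per library used a prior count of 2.

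Before the data were examined, 31 gene lists for kidney cell types, immune cells, injury, metabolism, stress and neighbouring tissues were fixed, as were the design, the alternatives and the rule for naming genes. Of the lists, 29 with at least 3 tested members were tested, and the other 2, Xist and genes of chromosome Y, were only counted per library. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the members move one way on balance and makes no comparison with other genes. List p-values were adjusted over the lists of a comparison. Members are also counted as adjusted over the list alone.

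Named genes included Nphs1, Podxl, Synpo and Wt1 in every comparison with control. To these were added, per comparison with control, the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 whose 3 toxin libraries all lay on the same side of all 3 controls. For each list the 2 members with the smallest adjusted p were named. Comparisons between days named the 3 largest changes in each direction under the same conditions. Not every gene named by these rules is printed. Other genes named in the text come from tests, some of them chosen after the values were seen.

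The fit was tested on simulated counts of 18092 genes with 200 changed genes per day, as many raised as lowered. Apart from these genes all groups had the mean control profile. Of genes changed 2-fold, 73, 66 and 70% were recovered in the simulations of day 5, day 14 and day 21, and of those changed 4-fold, 99, 100 and 97%. Unchanged genes called numbered 12, 5 and 12. The data had many more changes, TMM factors that differed between groups and a library apart from its group. The simulation held none of these, so its shares may not carry over to the data.

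The alternatives were median-of-ratios size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a CPM of at least 1 in 3 libraries, a minimum absolute log2 fold change of 1, the replicate number as a block, a fit of only the 6 libraries compared, and leaving out each library in turn. Scaling to library totals alone, and fits without day-21 replicate 2 for comparisons that do not include it, were chosen after seeing the data. Because the comparisons with control share 3 libraries, overlaps between days were set beside 10 simulations of unchanged groups against the same controls. No library was left out of the main results. The reference annotation of another genome build was not used here.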

Results

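RNA from whole kidneys of Pod-TRECK mice was measured by poly(A)-selected RNA sequencing. These mice carry a diphtheria toxin receptor in podocytes, the epithelial cells that form the filtration slits of the glomerulus, so that diphtheria toxin removes that cell type. Mice received 100 ng of toxin and kidneys were collected after 5, 14 or 21 days, and control mice received no toxin. There were 4 groups of 3 mice, 12 libraries in all. The deposited table gave between 31023852 and 46420299 counts per library, and 19821 of its 56722 genes had enough counts to be tested. Fold changes are on the log2 scale with the standard error of the fit, and every comparison had n = 3 libraries per group. Rises and falls are relative to TMM-scaled library sizes, while ratios given with counting intervals are relative to library totals.

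The libraries separated by group except for 1. The first principal component held 66.2% of the variance and the second 11.4%. Day-21 replicate 2 lay at -36.8 on the first component, while day-21 replicates 1 and 3 lay at 73 and 80.1. The lowest rank correlation within a group was 0.951 with this library and 0.986 without it. Nphs1, the slit diaphragm protein nephrin, was at 4.05 log2 CPM in day-21 replicate 2, against -1.11 and -0.81 in the other day-21 libraries and 4.33 to 4.63 in controls. Because all groups shared 1 estimate of the spread, this library also widened the errors of comparisons that did not include it, and values without it are also given. Transcripts of the mitochondrial genome took 22.9 ± 0.684% (SD, n = 3) of counts in controls, 19.1 ± 0.892% at day 5, 9.22 ± 0.238% at day 14 and 14.9 ± 5.42% at day 21. Day-21 replicate 2 was at 21.1%, and day-21 replicates 1 and 3 were at 11.8% each.

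**Figure D1:**
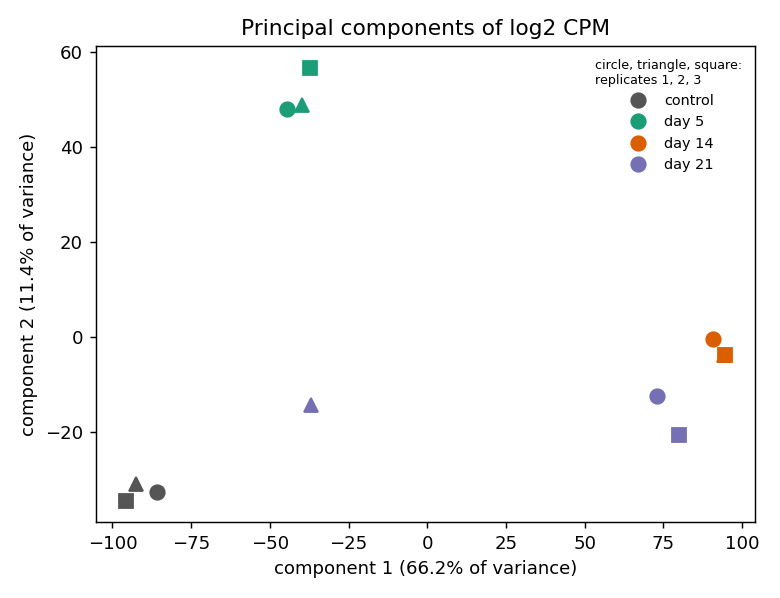
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis; colours are groups and marker shapes are replicates. Day-21 replicate 2 lies at -36.8 on the first component and the other day-21 libraries lie at 73 and 80.1.

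The comparison of day 5 with control asked what followed early after toxin. Podocyte transcripts fell, and transcripts of cell division and of injured tubules rose. Wt1, a transcription factor of podocytes, fell by 2.32 ± 0.28 on the log2 scale (adjusted p = 0.000389), Podxl, the podocyte surface sialomucin, fell by 1.36 ± 0.26 (adjusted p = 0.00574), and Synpo, an actin-binding protein of foot processes, fell by 0.93 ± 0.12 (adjusted p = 0.000484). Nphs1 (chromosome 7, positions 30157740 to 30186648 of GRCm39) fell by 3.88 ± 1.11 (adjusted p = 0.0381). Without day-21 replicate 2, Nphs1 changed by -3.87 ± 0.22 (adjusted p = 5.49e-07).

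Of the 27 podocyte genes measured, 16 fell, 2 rose and 9 did not pass at day 5. Adjusted over the list alone, 19 fell and 3 rose. Ptpro, a receptor tyrosine phosphatase of podocytes, fell by 3.39 ± 0.51 and Thsd7a fell by 1.89 ± 0.22. The list was lower than other genes by camera with a preset correlation (adjusted p = 1.49e-10), and had an adjusted p = 0.15 with an estimated correlation. In the fit without day-21 replicate 2, 20 fell and 4 rose, and the list passed with an estimated correlation (adjusted p = 0.028).

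All 26 cell cycle genes rose at day 5, with a median log2 fold change of 3.68, and all 26 also rose adjusted over the list alone. Mcm3, a subunit of the replicative helicase, rose by 2.22 ± 0.15 and Kif11, a mitotic kinesin, by 3.42 ± 0.24. This list also passed with an estimated correlation (adjusted p = 0.0419). Of 24 tubular injury genes, 16 rose and 8 did not pass, and 22 rose adjusted over the list alone (adjusted p = 0.0601 with an estimated correlation). With day-21 replicate 2 left out, 22 rose over all genes and the injury list passed with an estimated correlation (adjusted p = 0.00441), as did the cell cycle list (adjusted p = 0.028). Havcr1, the kidney injury molecule KIM-1, rose by 6.43 ± 0.29, from a mean of 2.59 CPM to 224 CPM. Krt20 rose by 6.66 ± 0.88, Timp1, an inhibitor of matrix metalloproteinases, by 6.05 ± 0.76, and the 3 fibrinogen chain genes Fgb, Fgg and Fga by 5.77 ± 0.31, 5.62 ± 0.36 and 5.22 ± 0.33.

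Inflammatory and matrix genes rose in part. Of 25 cytokine and NF-kB genes, 19 rose and 6 did not pass (19 adjusted over the list alone), with adjusted p = 0.0954 with an estimated correlation. Nfkb2 rose by 1.85 ± 0.17. Cxcl2, a neutrophil chemokine, had 643 counts in the day-5 libraries together against 5 in the controls, a ratio of 131 with a 95% counting interval of 56 to 406. Of 29 extracellular matrix genes, 14 rose and 15 did not pass (20 rose adjusted over the list alone; adjusted p = 0.354 with an estimated correlation), with Tnc, tenascin C, at 2.81 ± 0.37. Of 15 complement genes, 4 rose and 11 did not pass (6 rose adjusted over the list alone; adjusted p = 0.281 with an estimated correlation). Cfi rose by 1.63 ± 0.16 and C3 by 4.58 ± 0.55. Of 15 immediate early genes 6 rose (8 adjusted over the list alone; adjusted p = 0.354 with an estimated correlation), and of 15 p53 target genes 5 rose (5 adjusted over the list alone; adjusted p = 0.0601 with an estimated correlation). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose by 4.47 ± 0.56. In the fit without day-21 replicate 2, 20 cytokine and NF-kB, 23 matrix, 11 complement, 11 immediate early and 8 p53 target genes rose, with adjusted p = 0.00807, 0.178, 0.0497, 0.164 and 0.00807 with an estimated correlation.

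Among macrophage and monocyte genes 4 of 20 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.743 with an estimated correlation). Cd14 rose by 2.57 ± 0.31, and Csf1r, the receptor for colony stimulating factor 1, fell by 0.68 ± 0.1. Of 20 cholesterol synthesis genes 12 fell and 8 did not pass (13 fell adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), among them Insig1, which fell by 1.21 ± 0.14. Of 14 genes of the loop of Henle and distal tubule 5 fell (6 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation), and of 15 collecting duct genes 3 fell (6 adjusted over the list alone; adjusted p = 0.281 with an estimated correlation). Wnk4 fell by 1 ± 0.07 and Aqp3, a water channel, fell by 1.12 ± 0.16. Of 24 proximal tubule genes 0 passed at day 5 in edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 were lower, DESeq2 called 1 lower and limma-voom called 0, and without day-21 replicate 2, 12 of them fell (adjusted p = 0.3 with an estimated correlation). In that fit 10 macrophage and monocyte genes rose and 1 fell, and 18 cholesterol synthesis, 11 loop and distal tubule and 6 collecting duct genes fell, with adjusted p = 0.3, 0.0398, 0.00807 and 0.279 with an estimated correlation. Dbp and Per3, genes of the circadian clock, fell, with log2 fold changes of -4.67 ± 0.3 and -3.4 ± 0.23. Shisa3 fell by 3.5 ± 0.61 and Chrdl1 fell by 2.32 ± 0.65.

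In all, 2945 genes changed at day 5, of which 1936 rose and 1009 fell, so that 65.7% rose, against 77.7% when counts were scaled to library totals alone. Without day-21 replicate 2 the count was 6691, with 3598 rises and 3093 falls (53.8% rose), and in a fit of the 6 libraries compared it was 6982, with 3512 and 3470 (50.3% rose), so the excess of rises depends on the fit. Leaving out control replicate 1 or 3 gave 1764 or 1625 genes, and leaving out day-5 replicate 2 or 3 gave 1766 or 1570. The calls for Nphs1 and Chrdl1 were lost when any 1 of the 6 libraries compared was left out.

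**Figure D2:**
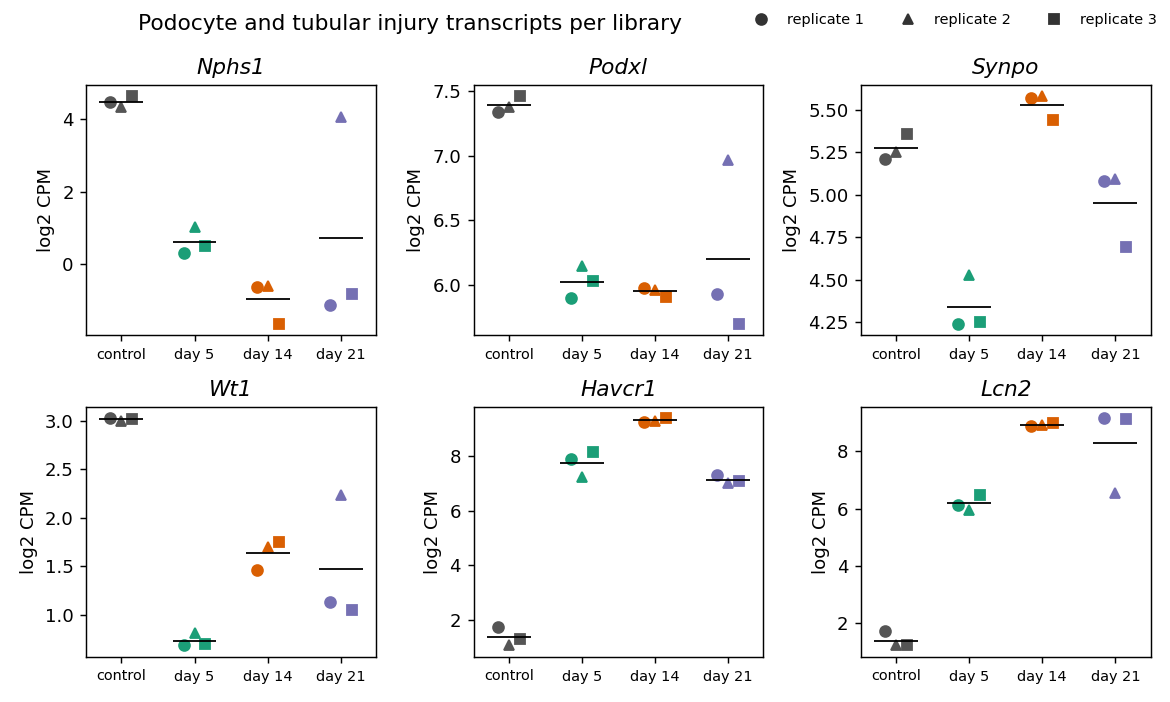
Log2 CPM of 4 podocyte genes (Nphs1, Podxl, Synpo, Wt1) and 2 tubular injury genes (Havcr1, Lcn2) in each library, by group; points are libraries, marker shapes are replicates and bars are group means. In day-21 replicate 2, Nphs1 is at 4.05, near the controls, while Havcr1 is at 7.02.

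The comparison of day 14 with control covered a later stage. Proximal tubule transcripts fell and macrophage, cytokine, complement and injury transcripts rose. All 24 proximal tubule genes fell, with a median log2 fold change of -2.83 (all 24 adjusted over the list alone; adjusted p = 0.405 with an estimated correlation, and 0.0301 without day-21 replicate 2). Slc22a7, an organic anion transporter, fell by 9.84 ± 1.99, Slc7a13, an amino acid transporter, fell by 8.69 ± 1.86, and Pck1, an enzyme of gluconeogenesis, fell by 2.3 ± 0.24. Cyp2d12, Pzp, Akr1c14 and Dnase1 fell, with log2 fold changes of -8.59 ± 1.74, -7.87 ± 1.57, -7.25 ± 1.58 and -7.22 ± 1.31.

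Mitochondrial and lipid oxidation genes also fell at day 14. All 19 oxidative phosphorylation genes fell (median -1.39; 19 adjusted over the list alone; adjusted p = 0.372 with an estimated correlation), as did all 13 protein-coding genes of the mitochondrial genome (median -2.06; 13 adjusted over the list alone; adjusted p = 0.366 with an estimated correlation). Of 20 fatty acid oxidation genes 18 fell and 2 rose (the same numbers adjusted over the list alone; adjusted p = 0.405 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 1.41 ± 0.15. The counts of these 3 lists were the same without day-21 replicate 2, with adjusted p = 0.0897, 0.0301 and 0.0425 with an estimated correlation. Reads of mitochondrial genes could not be told from those of nuclear copies: 4 such copies on chromosome 1 took between 1.06 and 1.43% of all counts each, so values of single mitochondrial genes are uncertain.

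All 20 macrophage and monocyte genes rose at day 14, with a median log2 fold change of 3.62 (20 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation). Adgre1, which encodes F4/80, rose by 3.2 ± 0.14 and the chemokine receptor gene Ccr2 by 4.13 ± 0.21. All 25 cytokine and NF-kB genes rose (25 adjusted over the list alone), 14 of 15 complement genes rose (14), 15 of 17 T and NK cell genes rose (16) and 18 of 21 interferon genes rose (18), each with adjusted p = 0.124 with an estimated correlation. Ccl2, a monocyte chemokine, rose by 6.99 ± 0.34, C3 by 7.45 ± 0.63, Lck by 2.28 ± 0.2 and Oasl2 by 2.2 ± 0.2. Of 24 tubular injury genes 22 rose (23 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation), with Havcr1 at 7.93 ± 0.31, Lcn2, neutrophil gelatinase-associated lipocalin, at 7.57 ± 0.65, Krt20 at 7.47 ± 0.89 and Vcam1 at 6.45 ± 0.35. Of 29 extracellular matrix genes 28 rose (28 adjusted over the list alone; adjusted p = 0.308 with an estimated correlation), including Col3a1 at 3.44 ± 0.33 and Tgfb1 at 2.07 ± 0.22. Of 26 cell cycle genes 24 rose (24 adjusted over the list alone; adjusted p = 0.405 with an estimated correlation). In the fit without day-21 replicate 2, the macrophage list (20 rose) had adjusted p = 0.0172 with an estimated correlation, and the cytokine (25), complement (14) and injury (22) lists had 0.00909 each. The T and NK cell (16), interferon (18, and 1 fell), matrix (29) and cell cycle (24) lists had 0.312, 0.179, 0.179 and 0.495.

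Podocyte genes were mixed at day 14. Of 27, 17 fell, 4 rose and 6 did not pass (17 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.0501, and adjusted p = 0.566 with an estimated correlation). The list passed without day-21 replicate 2 (17 fell and 5 rose; adjusted p = 0.0022, and adjusted p = 0.32 with an estimated correlation). Nphs1 fell by 5.47 ± 1.22, Podxl fell by 1.44 ± 0.26 and Wt1 fell by 1.39 ± 0.27, while Synpo was at 0.25 ± 0.12 (adjusted p = 0.0782) and Ptgds, a prostaglandin D synthase, rose by 3.31 ± 0.3. Of 14 loop of Henle and distal tubule genes 11 fell (12 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation), with Slc12a1, the loop sodium-potassium-chloride transporter, among those that fell, at -1.89 ± 0.2. Of 15 collecting duct genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.416 with an estimated correlation), with a median of -0.44 that became 0.29 when counts were scaled to library totals alone. Of 20 cholesterol synthesis genes 14 fell and 2 rose (14 and 2 adjusted over the list alone; adjusted p = 0.413 with an estimated correlation), with a median of -0.68 that became 0.05 under library totals. Ren1, renin, fell by 1.97 ± 0.25. All 6 erythroid genes fell (6 adjusted over the list alone; adjusted p = 0.416 with an estimated correlation), but their mean score was -5.69 and -5.72 in day-14 replicates 1 and 2 and -2.74 in replicate 3. With day-21 replicate 2 left out, 12 loop and distal tubule genes fell and 1 rose, 8 collecting duct genes fell and 2 rose, 14 cholesterol synthesis genes fell and 2 rose, and 6 erythroid genes fell. Their adjusted p with an estimated correlation was 0.00909, 0.495, 0.179 and 0.45, and the collecting duct and erythroid lists no longer passed with the preset one (adjusted p = 0.0517 each).

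In all, 11890 genes changed at day 14, 60% of those tested, of which 6189 rose and 5701 fell. Without day-21 replicate 2 the count was 13572. Scaled to library totals alone, 13158 rose and 2211 fell, or 85.6% rises against 52.1%. The share was 49.6% with median-of-ratios factors, 50.3% in DESeq2 and 51.3% in limma-voom. It was 49.2, 48.6 and 48.5% without control replicates 1, 2 and 3, so whether rises or falls were more numerous depends on the fit. The TMM factors averaged 0.793 in controls and 1.31 at day 14, and dropping them moved the median log2 fold change of all genes by 0.73.

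**Figure D3:**
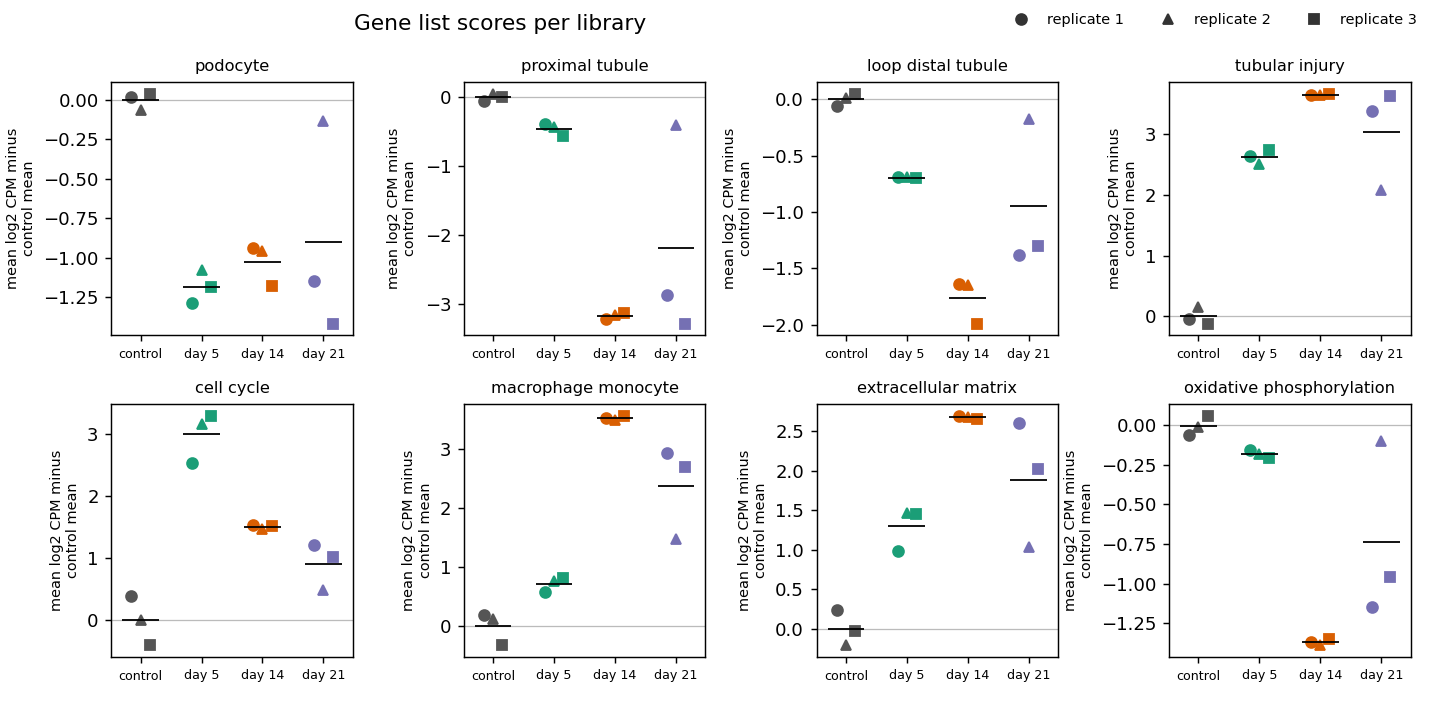
Mean log2 CPM of the members of 8 gene lists minus the control mean, per library and group; points are libraries, marker shapes are replicates and bars are group means. Day-21 replicate 2 lies closer to the controls than the other day-21 libraries in all 8 panels.

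The comparison of day 21 with control covered the last stage. Most injury, macrophage, cytokine, complement and matrix genes were above control. Of 24 tubular injury genes 22 rose (23 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation), with Lcn2 at 7.3 ± 0.65, Krt20 at 6.12 ± 0.88 and Havcr1 at 5.77 ± 0.28. Of 20 macrophage and monocyte genes 18 rose (18 adjusted over the list alone), of 25 cytokine and NF-kB genes 24 rose (24) and of 15 complement genes 14 rose and 1 fell (14 and 1), each with adjusted p = 0.133 with an estimated correlation. Lyz2, lysozyme, rose by 3.67 ± 0.26, Ccl2 by 4.66 ± 0.33 and C3 by 5.65 ± 0.58. Serpina3n rose by 6.82 ± 1.03, a call lost in limma-voom, and Timp1 by 6.65 ± 0.76. In the fit without day-21 replicate 2, 22 injury genes rose and 1 fell, 19 macrophage and 24 cytokine genes rose, and 14 complement genes rose and 1 fell, with adjusted p = 0.0236, 0.0346, 0.0344 and 0.0312 with an estimated correlation.

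Of 29 extracellular matrix genes 28 rose at day 21 (28 adjusted over the list alone; adjusted p = 0.359 with an estimated correlation). Mmp7, a matrix metalloproteinase, had 1391 counts in the day-21 libraries together against 5 in controls, a ratio of 335 with a 95% counting interval of 143 to 1030. Of 9 B and plasma cell genes 6 rose (7 adjusted over the list alone; adjusted p = 0.486 with an estimated correlation), with the immunoglobulin genes Jchain at 2.58 ± 0.53 and Igkc at 2.44 ± 0.51, calls lost in a fit of the 6 libraries compared (adjusted p = 0.0576 and 0.0605). Of 17 T and NK cell genes 7 rose (7 adjusted over the list alone; adjusted p = 0.276 with an estimated correlation), of 21 interferon genes 16 rose (17; adjusted p = 0.23 with an estimated correlation), and of 26 cell cycle genes 17 rose (21; adjusted p = 0.486 with an estimated correlation). With day-21 replicate 2 left out, 29 matrix, 8 of 11 B and plasma cell, 7 T and NK cell, 17 interferon and 21 cell cycle genes rose, and 1 B and plasma cell and 1 interferon gene fell. Their adjusted p with an estimated correlation was 0.189, 0.661, 0.609, 0.397 and 0.661, and the B and plasma cell and T and NK cell lists no longer passed with the preset one (adjusted p = 0.205 and 0.135), where 11 rather than 9 B and plasma cell genes were measured.

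Of 24 proximal tubule genes 11 fell at day 21 and 13 did not pass (15 fell adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). With day-21 replicate 2 left out all 24 fell, with a median log2 fold change of -2.73 against -1.44 with it (adjusted p = 0.0312 with an estimated correlation). Pck1 fell by 1.64 ± 0.23, and Hpd, an enzyme of tyrosine breakdown, fell by 3.12 ± 0.39. Azgp1 fell by 3 ± 0.62, Fcamr fell by 3.09 ± 0.88, Dnase1 fell by 3.08 ± 1.07 and Ldc1 fell by 2.93 ± 1.01. Cyp4b1-ps2 fell by 3.86 ± 1.27, and as a pseudogene it may share reads with related genes, so its value is uncertain. With day-21 replicate 2 left out, Fcamr, Dnase1 and Ldc1 were at -5.89 ± 0.31, -6.55 ± 0.28 and -6.73 ± 0.35 and Cyp4b1-ps2 at -6.65 ± 1.15. In that fit Pck1, Hpd and Azgp1 were at -1.87 ± 0.2, -3.86 ± 0.2 and -4.34 ± 0.38. The calls of Dnase1 and Ldc1 were lost when any control, or day-21 replicate 1 or 3, was left out, and that of Cyp4b1-ps2 when control replicate 1 or 2, or day-21 replicate 1 or 3, was. In a fit of the 6 libraries compared the calls of Azgp1, Fcamr, Dnase1, Ldc1 and Cyp4b1-ps2 were lost (adjusted p = 0.0561, 0.1, 0.143, 0.146 and 0.0894). Of 19 oxidative phosphorylation genes 12 fell (14 adjusted over the list alone; adjusted p = 0.486 with an estimated correlation) and of 13 mitochondrial genes 9 fell (12; adjusted p = 0.448 with an estimated correlation), against 19 and 13 without day-21 replicate 2 (adjusted p = 0.162 and 0.0598 with an estimated correlation).

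Of 27 podocyte genes 13 fell and 3 rose at day 21 (14 and 3 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). The counts were 19 and 3 without day-21 replicate 2 (adjusted p = 0.189 with an estimated correlation). Wt1 fell by 1.46 ± 0.27 and Podxl fell by 1.08 ± 0.26, and the call of Podxl was lost in a fit of the 6 libraries compared (adjusted p = 0.0757), as was that of Synpo (adjusted p = 0.139). Synpo fell by 0.31 ± 0.12 (adjusted p = 0.0494), was at 0.15 under library totals alone, and was at -0.19 without day-21 replicate 3, with the call lost when any control or day-21 library other than replicate 2 was left out. Nphs1, at -1.96 ± 1 (adjusted p = 0.13), did not pass. Without day-21 replicate 2, Nphs1 changed by -5.58 ± 0.3 (adjusted p = 3.06e-08). Aqp2, the vasopressin-regulated water channel, rose by 1.26 ± 0.23, and 5 of 15 collecting duct genes rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.78 with an estimated correlation), against 6 and 2 without day-21 replicate 2.

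In all, 8490 genes changed at day 21, of which 4821 rose and 3669 fell. With library totals alone 88.3% of the called genes rose, against 56.8%, and the share was 50.2% in limma-voom, 53.9% without day-21 replicate 2 and 78.8% in a fit of the 6 libraries compared. The count was 12738 without day-21 replicate 2, 5454 and 4918 without day-21 replicates 1 and 3, 5623 and 5168 without control replicates 2 and 3, and 1631 in a fit of the 6 libraries compared alone.

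**Figure D4:**
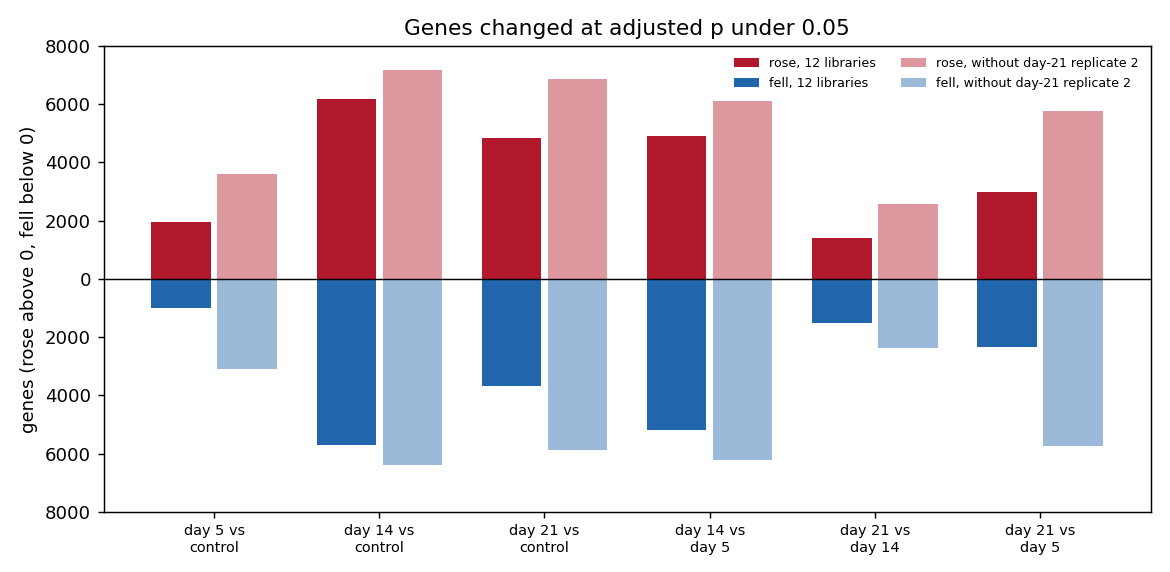
Genes that rose (above 0) and fell (below 0) at an adjusted p under 0.05 in each comparison, with all 12 libraries (dark bars) and without day-21 replicate 2 (pale bars). At day 21 the count goes from 8490 to 12738 without that library.

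Between day 5 and day 14, macrophage and monocyte genes rose while cell cycle and proximal tubule genes fell. Lyz2 rose by 4.97 ± 0.28 and Clec7a, a pattern recognition receptor of myeloid cells, by 4.46 ± 0.41, and 19 of 20 macrophage and monocyte genes rose (19 adjusted over the list alone; adjusted p = 0.151 with an estimated correlation). All 26 cell cycle genes fell, with a median of -1.76 (26 adjusted over the list alone; adjusted p = 0.315 with an estimated correlation), and all 24 proximal tubule genes fell, with a median of -2.39 (24 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). The counts of these lists were 20, 26 and 24 without day-21 replicate 2, with adjusted p = 0.0263, 0.426 and 0.0286 with an estimated correlation. Slc22a7 fell by 9.27 ± 1.97, Slc7a13 fell by 7.4 ± 1.77 and Slc22a19 fell by 7.01 ± 1.48. Ly6i was at 4.39 ± 1.46 (adjusted p = 0.0274), a call lost when day-5 replicate 2 or 3 or day-14 replicate 2 or 3 was left out, and with the replicate block. In all 10083 genes changed, of which 4905 rose and 5178 fell, against 12330 without day-21 replicate 2. With library totals alone 86.1% of the called genes rose, against 48.6%.

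Between day 14 and day 21, inflammatory genes fell and distal nephron genes rose. Cd83 fell by 2.39 ± 0.16, Vcam1 fell by 2.35 ± 0.29 and Ccl2 fell by 2.33 ± 0.25, and 15 of 25 cytokine and NF-kB genes fell (19 adjusted over the list alone; adjusted p = 0.143 with an estimated correlation). Of 14 loop of Henle and distal tubule genes 10 rose (11 adjusted over the list alone) and of 15 collecting duct genes 8 rose (11), each with adjusted p = 0.143 with an estimated correlation. In the fit without day-21 replicate 2, 17 cytokine genes fell, 11 loop and distal tubule genes rose and 1 fell, and 13 collecting duct genes rose, with adjusted p = 0.0348, 0.00419 and 0.0769 with an estimated correlation. Of 24 proximal tubule genes 4 rose (16 adjusted over the list alone; adjusted p = 0.49 with an estimated correlation), with a median of 1.46 that was 0.13 without day-21 replicate 2. Slc22a7 rose by 6.69 ± 1.92 and Dnase1 by 4.14 ± 1.14, but without that library they were at 0.4 ± 0.84 (adjusted p = 0.767) and 0.68 ± 0.23 (adjusted p = 0.0524). Dpys rose by 4.68 ± 1.26, and by 1.33 ± 0.4 without it. These 3 calls were lost when any day-14 library was left out, in limma-voom and with the replicate block. In all 2893 genes changed, of which 1393 rose and 1500 fell, against 4951 without day-21 replicate 2, 4874 without day-21 replicate 1, between 852 and 1216 when a day-14 library was left out, and 263 in a fit of the 6 libraries alone. With library totals alone 15.8% of the called genes rose, against 48.2%, and the share was 40.1% in limma-voom, 52.2% without day-21 replicate 2 and 21.3% in the fit of the 6 libraries.

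Between day 5 and day 21, all 26 cell cycle genes fell, with a median of -2.35 (26 adjusted over the list alone; adjusted p = 0.227 with an estimated correlation), and 16 of 20 macrophage and monocyte genes rose (19 adjusted over the list alone; adjusted p = 0.285 with an estimated correlation). Without day-21 replicate 2, 26 cell cycle genes fell and 20 macrophage and monocyte genes rose (adjusted p = 0.408 and 0.0788 with an estimated correlation). Igha rose by 3.77 ± 0.72 and Oit1 by 3.69 ± 0.67, a call lost in a fit of the 6 libraries (adjusted p = 0.0635), and Apoa4, Igfbp1 and Depp1 fell, with log2 fold changes of -3.51 ± 0.41, -3.5 ± 0.43 and -3.45 ± 0.29. In all 5325 genes changed, of which 2983 rose and 2342 fell. The count was 11506 without day-21 replicate 2, 3101 and 2589 without day-21 replicates 1 and 3, 2653, 2334 and 2089 without day-5 replicates 1, 2 and 3, and 506 in a fit of the 6 libraries alone. With library totals alone 86.9% of the called genes rose, against 56%, and the share was 45.2% in limma-voom, with 2519 rises and 3048 falls, and 50.1% without day-21 replicate 2, with 5764 and 5742, so the balance depends on the fit. Podocyte genes had a median of 0.64 in this comparison, which was 0.06 without day-21 replicate 2.

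Across the 3 days together, 13107 genes differed from control on at least 1 day by the joint test, 66.1% of those tested. Counting calls per day, 1183 genes rose and 542 fell on all 3 days, 1725 in total, so that 68.6% rose. Without day-21 replicate 2 there were 4585, with 2377 rises and 2208 falls (51.8% rose), so the excess of rises depends on that library. Days 14 and 21 shared 4094 rises and 3334 falls, against 1505 and 1055 for independent lists of the same sizes. Days 5 and 14 shared 1480 rises and 717 falls, against 605 and 290, and days 5 and 21 shared 1242 and 579, against 471 and 187. The 3 comparisons share the control libraries: over 10 simulations of unchanged groups no gene was called in common, and log2 fold changes correlated at 0.514, 0.508 and 0.513 across genes, where the observed correlations were 0.636, 0.633 and 0.901 for days 5 and 14, 5 and 21, and 14 and 21. Genes are not independent replicates. The covariances were 0.766, 0.552 and 1.445 against a simulated covariance of 0.056 for each pair of days. The 3 controls were too few to split into 2 sets of at least 2, so part of the excess may come from the shared controls.

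The counts of called lists carry little weight beyond their members. Camera with the preset correlation called 16, 20 and 20 of 29 lists at days 5, 14 and 21, and 18, 20 and 17 between day 14 and day 5, day 21 and day 14, and day 21 and day 5. With an estimated correlation 1 list was called at day 5 and 0 in the other 5 comparisons, where between 3 and 9 lists had an unadjusted p under 0.05 and fry called between 9 and 24. In fits of the 6 libraries compared, another split of the same libraries called at least as many lists with the preset correlation in 5 of the 6 comparisons. Between day 21 and day 5 the real split called 19 and the highest other split 17. In every other split each side kept most libraries of a different real group, so part of the real difference remained. These splits therefore cannot show how many lists would be called without a group difference. When day-21 replicate 2 was left out, an estimated correlation called 8, 10 and 7 lists at days 5, 14 and 21.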

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

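The tests of the wrong label and of the RNA mixture, the comparison of clock genes between days, and the spread of the proximal tubule falls were chosen after the results were seen.

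Named genes that rose on 1 day and fell on another are listed here, each with the tested difference between the days; other differences between days are in the comparisons between days. Ren1, renin, rose by 1.58 ± 0.24 at day 5 and fell by 1.97 ± 0.25 at day 14, a difference of -3.55 (adjusted p = 1.69e-05), and the difference between day 21 and day 5 was -3.13 (adjusted p = 0.000226). Csf1r was at -0.68 ± 0.1 and 0.72 ± 0.1 at days 5 and 14, a difference of 1.40 (adjusted p = 1.75e-05). Ighm, an immunoglobulin heavy chain, differed between day 14 and day 5 by 2.74 (adjusted p = 4.27e-05) and between day 21 and day 5 by 1.56 (adjusted p = 0.00258). Apoa1 differed by -4.10 (adjusted p = 4.06e-05) and -2.46 (adjusted p = 0.00125) in the same comparisons. Gsr differed between day 14 and day 5 by -1.25 (adjusted p = 3.74e-05), and Aqp2 between day 21 and day 5 by 2.05 (adjusted p = 0.000668). Calls on 1 side of some reversals depend on the fit. The day-5 fall of Ighm was lost without control replicate 1 or 2, without any day-5 library and in limma-voom, and that of Aqp2 without control replicate 3 or any day-5 library. The day-5 rise of Apoa1 was lost without control replicate 1 or 2 or day-5 replicate 3, and its day-21 fall without control replicate 3 or day-21 replicate 1 or 3 and in a fit of the 6 libraries compared. Under library totals the falls of Ighm and Aqp2 at day 5, Gsr at day 14 and Apoa1 at day 21 were lost. These were then at -0.67, -0.65, -0.07 and -0.61. Without the low-count filter the falls of Ighm at day 5 and Apoa1 at day 21 were lost, at -0.81 and -1.07.

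Day-21 replicate 2 stood apart from the other day-21 libraries. A control library under a wrong label is argued against, since 24 of 24 tubular injury genes in it lay above all 3 controls, where the other day-21 libraries had 22 and 23. A mixture of control RNA with RNA like that of the other day-21 libraries stays open. The median control share it would need was 0.79 from 13 podocyte genes and 0.85 from 23 tubular injury genes, a difference of -0.06, although Havcr1 gave 0.36. Of 22 lists 3 had a median share more than 0.25 from that of the injury genes: T and NK cell genes at 0.48, B and plasma cell genes at 0.53 and adipose genes at 1.25. Of 20 fatty acid oxidation genes 13 lay above all 3 controls in CPM, which 1 share of RNA like these controls would not give, while a control mouse outside the 3 was not measured. A milder injury in this mouse may give the same values and was not tested apart from it.

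Dbp and Per3, clock genes, fell at day 5. Collection at another time of day may account for this: of 13 other clock genes measured, 10 passed in the direction it predicts and 0 in the other, with Arntl at 3.40 ± 0.39 and Tef at -1.99 ± 0.13. A loss of clock output that follows the extent of tubular injury stays open as well. At day 14 the injury list had a higher median log2 fold change than at day 5 (3.12 against 1.55). More of its genes had risen with all 12 libraries, but not without day-21 replicate 2. Of the 13 other clock genes 7 were nearer control at day 14 than at day 5 by the test between these days. Of the others 3 were further from it and 3 did not pass. Per2 differed by 2.01 ± 0.23 and Npas2 by -2.24 ± 0.33 towards control, and Nr1d1 by -2.48 ± 0.44 away from it. Against control, Dbp was also lower at days 14 and 21, by -2.87 ± 0.27 and -2.03 ± 0.26. Per3 was at -0.47 ± 0.2 (adjusted p = 0.0595) and -0.75 ± 0.2 (adjusted p = 0.0144) on these days. The labels give no collection time, which keeps both explanations open.

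Proximal tubule transcripts fell at day 14. Whether a lower share of proximal tubule RNA was the only cause stays open. The 24 members fell by unequal amounts, with an SD of 3.12 times their median standard error of 0.54. A lower share would give equal falls only if other cells held none of these transcripts, which was not measured, so the spread cannot decide this. Lower androgen-dependent transcription stays open: 8 other male-biased kidney genes had a mean log2 fold change of -3.32 (SD 2.16) against -3.17 (SD 1.70) for the list, and a one-sided exact permutation test over 10518300 regroupings gave p = 0.406. Female-biased kidney genes, which it predicts to rise, were mixed at day 14: Abcc3 rose by 2.86 ± 0.52 and Cyp4a14 rose by 1.56 ± 0.31, Prlr fell by 2.56 ± 0.44 and Cyp2a4 fell by 5.38 ± 1.10, and Slc7a12 did not pass. Reduced transcription in injured tubule cells may also contribute and was not tested.

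Other splits of the same libraries were counted for each comparison, in fits of 6 libraries. With 10 splits a share under 0.05 cannot be reached. The real split was the only 1 of the 10 to give as many genes in each comparison, with 6982, 13339 and 1631 genes at days 5, 14 and 21, 12793 between day 14 and day 5, and 506 between day 21 and day 5, where the highest other split gave 0. Between day 21 and day 14 it gave 263 and the highest other split 6. As many lists as the real split were called by camera in 4, 7 and 4 splits at days 5, 14 and 21, and in 9, 5 and 1 between day 14 and day 5, day 21 and day 14, and day 21 and day 5. The real values were 18, 20, 19, 17, 20 and 19 and the highest others 21, 23, 23, 21, 22 and 17. For the joint test of all days, 1 of 40 splits of the 12 libraries gave as many genes, the real one with 13107, and the highest other gave 6445. That is a share under 0.05 of the splits drawn. Other splits put unlike libraries into 1 group, which widens the spread and lowers their counts of genes, so this does not exclude chance. In the fits of 6 libraries, other splits also kept part of the real group difference, so their list counts cannot decide it either.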

How the results depend on the processing

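Scaling to library totals alone, and leaving out day-21 replicate 2 in comparisons that do not include it, were chosen after the results were seen. Median-of-ratios factors, DESeq2, limma-voom, both filters on low counts and the replicate block kept every count of changed genes within 1.5 times the main one. Over 232 gene results, 3175 of 3373 values under an alternative kept their direction and side of the threshold, 152 lost the call, 44 gained it and 2 reversed. These are named genes: over all genes, library totals called 1076 of the 11890 day-14 genes, 40 of the 8490 day-21 genes and 463 of the 10083 genes between day 14 and day 5 in the opposite direction. Over 174 list results the numbers were 1761 of 2001, 184, 54 and 2, and 33 uncalled values differed in sign. Under library totals Esam at day 14 was at 0.03 and Synpo at day 21 at 0.15, because the median of all genes moves by 0.73 and 0.49. Between day 21 and day 5, without day-21 replicate 2, the podocyte list was at 0.06 and the cholesterol synthesis list at -0.02. Leaving out other libraries gave up to 0.75 and 0.28. The podocyte scores at day 21 ran from -1.42 to -0.13, with replicate 2 closer to the controls than the other day-21 libraries, so this median depends on that library. For the cholesterol synthesis list the cause was not tested.

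A minimum absolute log2 fold change of 1, which can only lower a count, gave 1207, 6150 and 3728 genes at days 5, 14 and 21, 4593, 904 and 2134 between day 14 and day 5, day 21 and day 14, and day 21 and day 5, and 6553 for any day. In fits of the 6 libraries compared, the count was 6982 at day 5, 1631 at day 21, 263 between day 21 and day 14 and 506 between day 21 and day 5. Leaving out 1 library gave 1570 to 6691 genes at day 5, 10405 to 13572 at day 14, 4918 to 12738 at day 21, 7941 to 12330 between day 14 and day 5, 852 to 4951 between day 21 and day 14, 2089 to 11506 between day 21 and day 5, and 11220 to 15912 for any day. The highest came without day-21 replicate 2 in each, and all-day calls then numbered 4585. Called lists ranged from 15 to 18, 18 to 23 and 17 to 22 at days 5, 14 and 21, and from 15 to 18, 14 to 21 and 14 to 19 in the comparisons between days. With an estimated correlation camera called 1 list at day 5 and 0 elsewhere, where the preset correlation called 16 to 20, and fry called 9 between day 21 and day 14 and 10 between day 21 and day 5.

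The replicate numbers do not pair the libraries: 4 of 18 same-number pairs correlated above 0.1 (range -0.14 to 0.171) and 4 of 12 libraries correlated best with their own number. With the replicate block 2653, 11673 and 8218 genes were called at days 5, 14 and 21, and 9810, 2211 and 4825 between day 14 and day 5, day 21 and day 14, and day 21 and day 5. Of named genes called at days 5, 14 and 21, 11 of 53, 2 of 71 and 10 of 65 lost the call when a library was left out, and 3, 3 and 25 did in other settings, 22 of the 25 in the fit of the 6 libraries. Esam at day 14, which changed sign and also lost its call under library totals, is not in these counts. Genes with few control counts, such as Mc2r with 3, have wide counting intervals at this depth.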

Other observations

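The values in this part were looked at after the results were seen, and the gene lists were fixed earlier.

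Other gene groups moved less evenly. Of 17 endothelial genes 2 fell and 1 rose at day 5, 9 fell and 2 rose at day 14, and 4 fell and 1 rose at day 21 (3 and 1, 9 and 2, and 4 and 1 adjusted over the list alone). The median was -0.37 at day 14 and -0.23 at day 21, and 0.36 and 0.24 under library totals. Plat, tissue plasminogen activator, rose by 1.05 ± 0.15 at day 5 and 2.03 ± 0.15 at day 14, while Kdr, a receptor for vascular endothelial growth factor, fell by 1.10 ± 0.28 at day 21, a call lost in a fit of the 6 libraries compared (adjusted p = 0.0799). Of 12 mesangial and mural genes 1 rose at day 5, 7 rose and 2 fell at day 14, and 6 rose and 2 fell at day 21 (1, 8 and 2, and 6 and 2 adjusted over the list alone). Leaving out day-21 replicate 2 gave 4 rises of mesangial and mural genes and 2 rises and 4 falls of endothelial genes at day 5. Of 5 neutrophil genes 3, 4 and 4 rose on the 3 days (4 on each day adjusted over the list alone, with 1 fall at day 5), with adjusted p = 0.366 and 0.404 with an estimated correlation at days 14 and 21. The list no longer passed with the preset correlation at either day without day-21 replicate 2 (adjusted p = 0.0503 and 0.0805), but 7 rather than 5 genes were measured in that fit, of which 5 rose and 1 fell at day 5 and 6 and 5 rose at days 14 and 21. S100a9 had 115 counts in the day-14 libraries against 7 in controls, a ratio of 20.2 with a 95% counting interval of 9.51 to 51.4. Of 17 T and NK cell genes 1 rose at day 5 (1 adjusted over the list alone), and 2 without day-21 replicate 2. Of 9 B and plasma cell genes 1 fell at day 5 and 3 rose at day 14 (0 and 3 adjusted over the list alone).

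Stress response groups were mixed. Of 17 unfolded protein response genes 4 rose at day 5, 5 rose and 1 fell at day 14, and 3 rose and 1 fell at day 21 (6, 4 and 1, and 2 and 1 adjusted over the list alone). The list was called by camera at day 5, with adjusted p = 0.483 with an estimated correlation. Chac1 rose by 2.73 ± 0.34 at day 5, and Herpud1 fell by 1.28 ± 0.15 at day 14. Of 14 NRF2 target genes 4 rose and 1 fell at day 5, 4 rose and 8 fell at day 14, and 5 rose and 4 fell at day 21 (4 and 1, 4 and 9, and 5 and 4 adjusted over the list alone), with a day-14 median of -0.65 that was 0.08 under library totals. Of 20 fatty acid oxidation genes 3 rose at day 5, and 8 fell and 2 rose at day 21 (3, and 11 and 2 adjusted over the list alone; adjusted p = 0.628 with an estimated correlation at day 21), where Cyp4a14 rose by 3.04 ± 0.33. Of 15 p53 target genes 10 rose and 1 fell at day 14 and 10 rose at day 21 (the same adjusted over the list alone; adjusted p = 0.124 and 0.133 with an estimated correlation). Of 15 immediate early genes 8 rose and 2 fell at day 14 and 10 rose and 1 fell at day 21 (9 and 2, and 10 and 1 adjusted over the list alone; adjusted p = 0.426 and 0.486 with an estimated correlation). Of 21 interferon genes 5 rose at day 5 (10 rose and 2 fell adjusted over the list alone; adjusted p = 0.483 with an estimated correlation). At day 21, 6 of 14 loop of Henle and distal tubule genes fell and 2 rose (7 and 2 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation), and 10 of 20 cholesterol synthesis genes fell and 3 rose (11 and 4 adjusted over the list alone; adjusted p = 0.557 with an estimated correlation), with a median of -0.38 that was 0.09 under library totals. In the fit without day-21 replicate 2, day-5 counts were 12 rises and 2 falls of interferon genes (adjusted p = 0.563 with an estimated correlation), 5 rises and 3 falls of fatty acid oxidation genes, 7 rises of unfolded protein response genes (adjusted p = 0.563 with an estimated correlation) and 4 rises and 2 falls of NRF2 target genes. At day 21 it gave 5 rises and 7 falls of NRF2 target genes, so that falls outnumbered rises, and 3 rises and 2 falls of unfolded protein response genes. The p53 target list then had 10 rises and 2 falls at each of days 14 and 21 (adjusted p = 0.0301 and 0.036 with an estimated correlation), 16 fatty acid oxidation genes fell at day 21 (adjusted p = 0.162 with an estimated correlation), and 11 loop and distal tubule and 14 cholesterol synthesis genes fell at day 21 (adjusted p = 0.0588 and 0.233 with an estimated correlation).

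Among markers of neighbouring tissues and blood, adipose and erythroid scores differed between libraries of 1 group. The liver and pancreas score varied little within controls, day 5 and day 14 (SD 0.07, 0.04 and 0.12), and more at day 21 (SD 0.73). The adipose score ran from -4.52 to 1.04 at day 5, from -1.66 to 1.87 at day 14 and from -3.95 to 1.05 at day 21, and of 10 adipose genes 0, 1 and 1 fell in edgeR (0 on each day adjusted over the list alone), where at day 5 0 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. The erythroid score was -0.92, -0.16 and -5.17 in the day-21 libraries. Of 4 adrenal genes 1 rose on each day and 1 fell at day 14 (2 rose at day 5, and the same at the other days, adjusted over the list alone; adjusted p = 0.168 with an estimated correlation at day 5). Akr1b7 rose by 2.23 ± 0.22 at day 5. Of 10 urothelial genes 1, 5 and 3 rose on the 3 days (1, 3 and 3 adjusted over the list alone), and of 6 liver and pancreas genes 1 rose at day 5, 6 fell at day 14 and 5 fell at day 21 (2, 6 and 5 adjusted over the list alone; adjusted p = 0.127 and 0.23 with an estimated correlation at days 14 and 21, and 0.0172 and 0.0346 without day-21 replicate 2). Without that library the adrenal list no longer passed at day 5 with the preset correlation (adjusted p = 0.0704), 2 adrenal genes rose at days 5 and 21 and 2 fell at day 14, and 2 liver and pancreas genes rose and 2 fell at day 5. Rbmy, an RNA-binding protein gene of chromosome Y with related copies that can share reads, was at 7.49 ± 0.43 at day 14, and its value is uncertain. Counts of the chromosome Y genes ran from 4765 to 6543 per library and Xist had 1 to 3 counts in each.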
